A study of Danio rerio with 96 samples.

How the data were processed

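Whole zebrafish embryos were measured with TempO-Seq, a targeted assay in which pairs of detector oligonucleotides anneal to RNA, are ligated, amplified and sequenced, so that each feature is a probe target and not a whole transcript. The surrogate panel for zebrafish was used. Per the labels' protocols, embryos were kept in 0.1% dimethyl sulfoxide (DMSO), the vehicle control of chemical exposures, for 5 days up to 120 hours post fertilization, total RNA was extracted with a commercial kit, and libraries were pooled in equal amounts and sequenced on an Illumina instrument. No sample received another chemical. The authors deposited a table of raw read counts per feature, and per the submitters' processing notes the tools were bcl2fastq 2.20, fastp 0.23.2, STAR 2.7.10a, RSEM 1.3.3 and DESeq2 1.31.15. The genome build, the annotation and the step that made the counts are not given in the sources used here. The deposited counts were whole numbers with no normalization.

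The table held 3183 rows and 96 sample columns, all of which were used. Its rows carry no gene or probe name, so features are called by their row number, counted from 1, and no gene name, gene group or tissue marker list was used here. The lists of genes fixed before the data were examined (pathways, stress responses, tissues and cell types) therefore have no result. 6 rows were 0 in every sample. Total counts per sample ran from 3336312 to 6441627, with a median of 4498706. In the smallest library 3 counts, the upper limit that a count of 0 allows, equal 0.899 CPM (counts scaled to a common library total), and in the largest 0.466 CPM. Reads carry no molecular identifiers, so these limits cover counting error only.

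Samples were grouped by the number of embryos pooled (1, 5, 10 or 20) from the labels, with 24 samples in each group. Each group held 3 extraction batches of 8 samples. Embryos were exposed in Petri dishes, per the labels' protocols. The labels do not say whether samples of a batch came from separate dishes or parents, so p-values measure the spread between these samples, which may be technical. No 2 columns were identical, and over all 336 pairs of samples from 1 batch the chi-square of their counts was at least 6.22 per degree of freedom, above counting error. Repeat libraries of 1 sample would exceed counting error too, so this does not exclude repeats, and each sample was counted once as the labels give it. Because a batch belongs to 1 pool size, pool sizes were compared on the 12 batch sums, the counts of the 8 samples of a batch added together. Batches, exposures and extraction dates within a pool size were compared on the 24 samples, and pool10 with pool1 of 1 exposure on 16 samples.

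Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after its filter on low counts and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. A feature is said to be called when its adjusted p was below that threshold. Spread within a batch was the square root of edgeR's common dispersion, estimated in each batch of 8 over the same features. Spread per feature was compared between pool20 and pool1 with limma 3.58.1 on absolute deviations of log2 CPM (prior count 2) from the batch mean, over the 2198 features with a mean count of at least 50. In that test single samples, and not batches, were the replicates. A feature was detected in a sample with at least 5 counts. Correlations over 12 batches were tested two-sided with 100000 permutations, and those over 7 batches and all differences between batch means with exact permutation tests. What a small comparison can recover was measured on real counts: 8 samples of 1 batch were split into 4 against 4, 200 features were changed 2-fold by binomial thinning, 100 in each arm, and the share called was averaged over 12 splits per pool size.

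The tests were checked on simulated data. For pool20 against pool1 on batch sums (3159 features, simulated dispersion 0.05), 78% of 200 features changed 2-fold and 100% of those changed 4-fold were recovered, with 9 and 8 false calls. The real batch sums had a common dispersion of 0.172, larger than the simulated one, so these shares are not those of the real comparison. For the pool1 batches (2692 features, dispersion 0.4) 4% of 2-fold changes were recovered by the F test over the batches, and for the pool20 batches (3039 features, dispersion 0.03) 99%. The test of spread (2198 features) recovered 92.5% of features given an 8-fold larger dispersion in pool1, with 16 false calls.

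Alternatives fixed before the data were examined were DESeq2 1.42.0 as the test, its size factors in edgeR, no filter on low counts, single samples as replicates with and without the batch as a random effect, the replicate number as a block, each batch left out, thinned counts, other count minimums, and other sizes of the recovery test. A further alternative would leave out libraries under 1124677 counts, a set share of the median, and removed 0. Added after the data were examined were the comparisons of single batches and of 24 with 23 November, the relations within December, the comparisons of spread and detection by exposure, the slope, the averaging line, and these settings: the exposure month as a covariate, only pool1 and pool5 in the fit, the replicate number as a block in the exposure from 12 December, the results without 1 pool5 library, the comparison of samples 1 to 4 with samples 5 to 8 of a batch, that position as a term, and the results without samples 5 to 8 of the number-1 batches. Sample numbers within a batch are taken from the labels. Adjustment over exact comparisons was widened from each quantity to all 13 when those by exposure were added. The rule for named features takes those with the greatest rise and fall among called features with a mean of at least 10 CPM. It was written for 8 each way, and, as rows have no names, was reduced to 2 each way. For spread among single embryos it takes the greatest dispersions, reduced from 15 features to 2. Figures were drawn with matplotlib 3.10.9.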

Results

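The 96 samples were vehicle-control zebrafish embryos at 120 hours post fertilization, in pools of 1, 5, 10 or 20 embryos (pool1, pool5, pool10 and pool20), with 24 samples per pool size and 864 embryos in total. Per the series design, the pool sizes were compared to choose a sample design for dose-response studies. Totals averaged 4066542 ± 593023 counts (SD, n = 24) in pool1, 5075359 ± 622950 in pool5, 4538980 ± 520762 in pool10 and 4739873 ± 576837 in pool20. They ran from 3336312 to 5343504 in pool1, from 4278771 to 6441627 in pool5, from 3825046 to 5577291 in pool10 and from 3791022 to 5870280 in pool20. The 10 most abundant features took 28.4% ± 2.08 of the counts in pool1, 29.8% ± 1.62 in pool5, 26.9% ± 2.49 in pool10 and 26.6% ± 1.62 in pool20 (SD, n = 24 each).

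Pool size, exposure and extraction date overlapped only in part. Batches 1 and 2 of pool10 were exposed from 2 November and extracted on 23 and 24 November. All pool20 batches were exposed from 4 November, and batches 1, 2 and 3 were extracted on 23 November, 24 November and 15 December. All pool5 batches and pool1 batches 1 and 2 were exposed from 12 December and extracted on 17 December. Batch 3 of pool1 and batch 3 of pool10 were exposed from 13 December and extracted on 18 December. November exposures were extracted 14 to 36 days after the exposure ended and December exposures on the day it ended.

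The main axis of expression across the 96 samples followed the extraction date. The first principal component of log2 CPM, over 3108 features, held 40.4% of the variance. Mean positions on it were -58.3 ± 7.46 and -44.2 ± 4.83 (SD, n = 8) in the pool10 and pool20 batches of 24 November and -34.0 ± 6.86 and -26.6 ± 2.32 in those of 23 November. The pool20 batch of 15 December lay at -6.66 ± 8.55, and the 7 batches of 17 and 18 December lay between 13.1 and 36.7. Extraction batch accounted for 96.1% of the variance on that axis, extraction date for 91.3%, exposure month for 79.9% and pool size for 57.7%. These shares overlap because the labels are confounded, and they are not adjusted for the number of groups, which is largest for the batch.

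The second axis, with 9.46% of the variance, parted samples 1 to 4 from samples 5 to 8 in batches numbered 1, a comparison added after the data were seen. Samples 1 to 4 and 5 to 8 averaged -3.77 ± 4.26 and -47.98 ± 13.1 in pool1 batch 1 (SD, n = 4 each), 6.04 ± 6.31 and -31.99 ± 21.8 in pool5 batch 1, and 3.31 ± 1.16 and -8.81 ± 4.66 in pool10 batch 1. These sets did not overlap (exact permutation p = 0.0286 in each, the smallest that 4 against 4 samples allow, adjusted over 12 batches 0.0857). The adjustment does not cover the choice of the axis and of the cut between samples 4 and 5. Both were chosen after the data were seen, so the p-values on this axis describe these samples only. In pool20 batch 1 they averaged -0.064 ± 1.603 and -5.02 ± 3.56 (exact permutation p = 0.0571, adjusted 0.137). Pool5 batch 3 also had an exact permutation p of 0.0286 (adjusted 0.0857), with a smaller difference of samples 5 to 8 from samples 1 to 4, at -3.03. Sample 8 of pool1 batch 2, outside the number-1 batches, lay at -34.2. That is within the range of samples 5 to 8 of pool1 batch 1, from -65.2 to -33.9. A low position on this axis was thus not confined to the number-1 batches. By edgeR 565 of 2571 features differed between the sets in pool1 batch 1, 61 of 2664 in pool5 batch 1, 311 of 2997 in pool10 batch 1 and 0 of 2976 in pool20 batch 1 (252 at an unadjusted p under 0.05). Of the other 8 batches, pool20 batch 2 had 26 and the others 0 each, with 116 to 261 at an unadjusted p under 0.05 by edgeR. Across features, which are not independent replicates, the differences correlated at 0.39 to 0.79 over the 6 pairs of number-1 batches, with a median of 0.47, and at a median of 0.087 over the 60 other pairs. The number-1 batches were extracted on different dates, but the labels number their libraries consecutively, from pool1 through pool5 and pool10 to pool20. Their differences on the second axis shrank in that order, at -44.2, -38.0, -12.1 and -4.95. It is also the order of pool size, and library order was not tested as a source of this pattern.

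**Figure D1:**
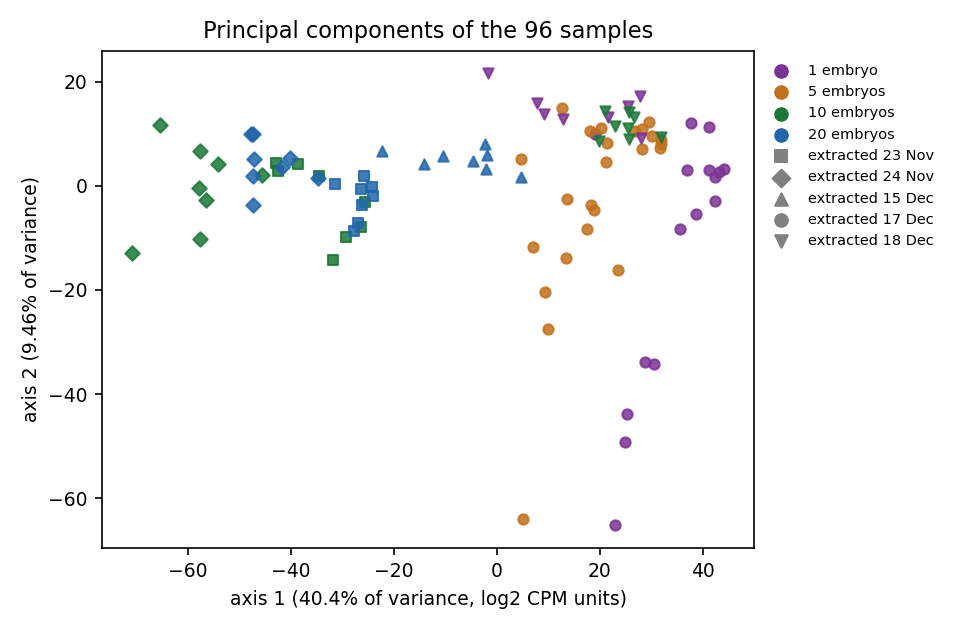
Principal components of log2 CPM in the 96 samples, with axis 1 (40.4% of the variance) across and axis 2 (9.46%) up, in log2 CPM units. Each point is a sample, coloured by embryos per sample and shaped by extraction date. The samples extracted in November, all of 10 or 20 embryos, lie to the left and those of 17 and 18 December, of 1, 5 or 10 embryos, to the right, and pool10 is the 1 size found on both sides.

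The spread between samples of a batch was widest with single embryos and fell with pool size. The common biological coefficient of variation within a batch was 64.3% ± 6.63 (SD, n = 3 batches) for single embryos, 32.4% ± 14.1 for pools of 5, 20.8% ± 4.66 for pools of 10 and 16.7% ± 1.91 for pools of 20. The 3 pool5 batches ranged from 18.9% to 46.9%. 1 library, sample 6 of pool5 batch 1, set the top of that range: without it the batch had 33.7% and pool5 28.0% ± 7.97, a value chosen after the data were seen. Part of the spread in the number-1 batches followed position: with samples 1 to 4 and 5 to 8 fitted apart, also added after the data were seen, pool1 batch 1 had 60.9% in place of 70.16% and pool5 batch 1 had 38.7%, and the pool means were 60.6% ± 4.04, 29.3% ± 10.04, 19.2% ± 5.20 and 15.7% ± 1.52. Samples 1 to 4 of pool5 batch 1 alone had 25.9%. Averaging the mean single-embryo dispersion over the pool would give 28.9% for 5 embryos, 20.4% for 10 and 14.4% for 20.

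Over the 12 batches the coefficient of variation fell with log2 pool size (Pearson r = -0.93, permutation p = 1.0e-04, adjusted over 4 relations 4.0e-04; Spearman rho = -0.89, p = 4.4e-04, adjusted 0.00176). The 3 single-embryo batches lie farthest from the median pool size, and without 2 of them r lay between -0.88 and -0.86. Within the 7 batches of December exposures r was -0.91 (exact permutation p = 0.0214, adjusted 0.0286) and rho -0.93 (exact p = 0.0143, adjusted 0.0190). The 5 batches of November exposures are too few for a correlation. There pool10 was 1.37 times as variable as pool20, with an exact permutation p of 0.10 (adjusted over 13 comparisons 0.13), the smallest that 2 against 3 batches allow. The 5 batches of November exposures had a mean coefficient of variation of 0.192 as a fraction and the 7 of December exposures 0.438 (exact permutation p = 0.0366, adjusted over 13 comparisons 0.13), although the November batches were all of 10 or 20 embryos. Pool1 against each other pool size also had an exact p of 0.10 (adjusted 0.13), the smallest that 3 against 3 batches allow, with pool1 1.99 times as variable as pool5, 3.09 times as pool10 and 3.85 times as pool20. Within the exposure from 12 December pool1 was 2.097 times as variable as pool5 (exact permutation p = 0.20, adjusted 0.236). On log scales the dispersion changed with a slope of -0.92 ± 0.13 (SE, n = 12 batches) on pool size.

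**Figure D2:**
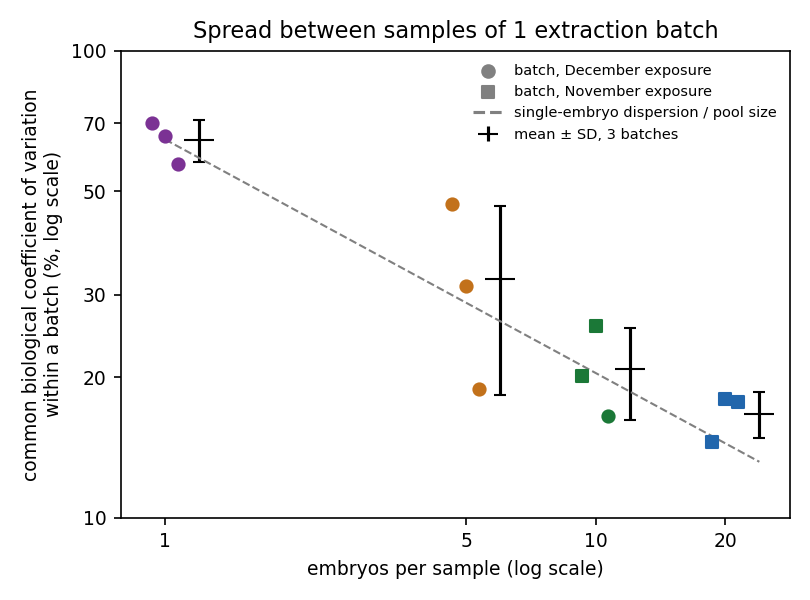
Common biological coefficient of variation (%, log scale) within each extraction batch of 8 samples against embryos per sample (log scale). Circles are batches of December exposures and squares of November exposures, black marks are the mean ± SD of 3 batches, and the dashed line is the mean single-embryo dispersion divided by the pool size. The means are 64.3%, 32.4%, 20.8% and 16.7% for 1, 5, 10 and 20 embryos.

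The reduction in spread covered most of the panel. Of 2198 features, 2049 (93.2%) were less variable in pool20 than in pool1 by limma on absolute deviations with Benjamini-Hochberg adjustment at 0.05. None was more variable in pool20, at the adjusted threshold or at an unadjusted p under 0.05 (0 features each), also by that test. The median SD of log2 CPM within a batch was 0.56 for single embryos, 0.39 in pool5, 0.27 in pool10 and 0.20 in pool20. Features with an SD above 1, a 2-fold spread, numbered 401 in single embryos, 41 in pool5, 8 in pool10 and 1 in pool20. With samples 1 to 4 and 5 to 8 of each batch centred apart, added after the data were seen, these numbers were 347, 22, 7 and 1. The order of features by variance was partly kept: across these features, which are not independent replicates, the Spearman correlation of the variance with that in pool1 was 0.75 in pool5, 0.72 in pool10 and 0.73 in pool20. Abundance was not held fixed in these correlations, so they do not separate the variability of a feature from its abundance. All pool20 samples came from an exposure of their own, so this comparison does not separate pool size from exposure.

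Features 2058 and 767 had the greatest dispersion among single embryos. Feature 2058 ranged from 0 to 64.6 CPM over the 24 single embryos with a median of 0.69 CPM, under the 0.899 CPM of 3 counts in the smallest library, and its dispersion was 4.50. In pool20 it averaged 9.56 ± 10.8 CPM (SD, n = 24). Feature 767 ranged from 0 to 36.2 CPM with a median of 0.48 CPM and a dispersion of 4.26, and averaged 18.2 ± 7.70 CPM in pool20 (SD, n = 24). The SD of log2 CPM within a batch was 2.88 for feature 2058 and 2.04 for feature 767 in single embryos, against 0.76 and 0.47 in pool20.

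Larger pools and the November batches gave more detected features. Features with at least 5 counts numbered 2630 ± 78.1 (SD, n = 3 batches) in pool1, 2796 ± 47.3 in pool5, 2976 ± 182 in pool10 and 3040 ± 50.9 in pool20. The number rose with log2 pool size over the 12 batches (Pearson r = 0.87, permutation p = 2.5e-04, adjusted over 4 relations 5.0e-04; Spearman rho = 0.82, p = 0.00258, adjusted 0.00516). Without 2 of the single-embryo batches r lay between 0.75 and 0.84. Within the 7 December batches r was 0.79 (exact permutation p = 0.0429, adjusted 0.0429) and rho 0.77 (exact p = 0.0571, adjusted 0.0571), so rho did not pass the threshold.

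The 5 batches of November exposures held 3056 features on average and the 7 of December exposures 2720, a difference of 336 (exact permutation p = 0.00126, adjusted over 13 comparisons 0.0164), although the November batches were all of 10 or 20 embryos and include pool20 batch 3 by its label. Within November, pool20 had 39.8 fewer than pool10, which is a difference of -39.8 (exact permutation p = 0.40, adjusted 0.40). In the exposure from 13 December, pool10 had 2767 ± 47.4 and pool1 2720 ± 123 (SD, n = 8 samples each), which did not differ beyond the spread (exact permutation p = 0.326, adjusted 0.353). In the exposure from 12 December, pool5 had 211 more than pool1 (exact permutation p = 0.10, adjusted 0.13), the smallest p that 2 against 3 batches allow.

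**Figure D3:**
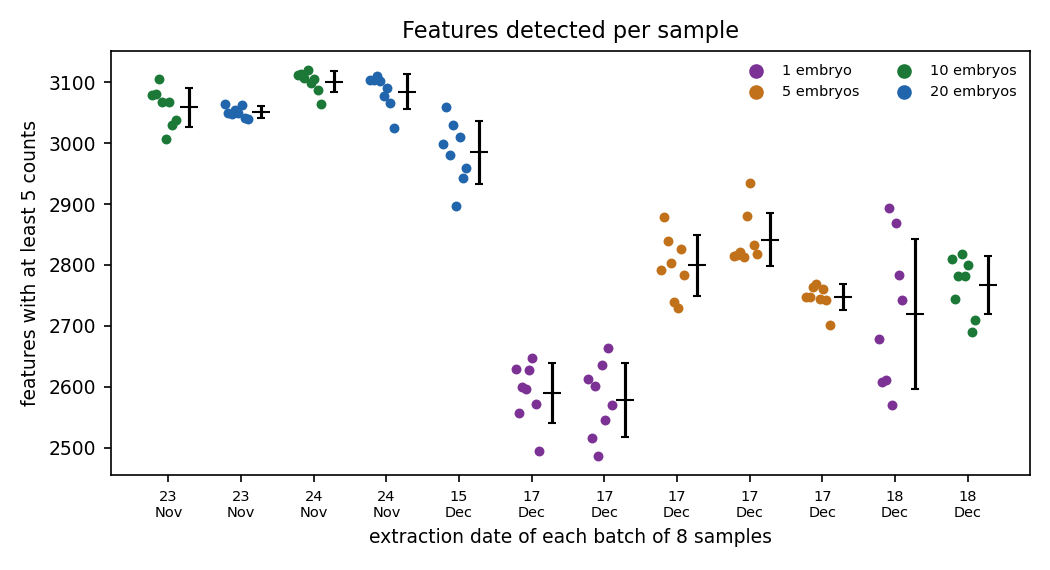
Features with at least 5 counts in each sample, by extraction batch in order of extraction date. Points are samples coloured by embryos per sample, and black marks are the mean ± SD of 8 samples. The pool10 batches of November hold 3059 and 3101 features on average and the pool10 batch of 18 December 2767.

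With the extraction batch as the replicate, edgeR called no feature between pool sizes and DESeq2 called some in each comparison. By edgeR's quasi-likelihood test on all 12 batch sums, 0 of 3159 features were called among the 4 pool sizes, with 523 at an unadjusted p under 0.05. The contrasts of pool5, pool10 and pool20 against pool1 each called 0, with 59, 576 and 663 at an unadjusted p under 0.05, and median absolute log2 changes of 0.18, 0.36 and 0.42. DESeq2 on the same sums called 251 among the 4 sizes and 1, 197 and 129 in the 3 contrasts. With single samples and the batch as a random effect limma called 693, 0, 649 and 689. The counts rested on 1 batch: without pool10 batch 3, the December one, edgeR called 772 among the 4 sizes, 953 for pool10 and 265 for pool20. In that fit every batch of 10 or 20 embryos was a November exposure and every batch of 1 or 5 a December one. Pool size and month cannot be told apart there, nor in pool20 against pool1 under any of these tests. With exposure month as a covariate, added after the data were seen, edgeR called 0 in all 4 results. Month itself, with pool size as a covariate and set by pool10 alone, was called in 463 of 3169 features. Without pool1 batch 3 edgeR called 1 feature in each contrast.

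Within the exposure from 12 December, which all pool5 batches share with pool1 batches 1 and 2, edgeR called 0 of 3084 features on the 5 batch sums. At an unadjusted p under 0.05 there were 174, DESeq2 called 9, and single samples without a batch term gave 157. Pool10 and pool1 shared the exposure from 13 December, with 1 batch of 8 samples each. There 193 of 2567 features were called in the 16 samples, 96 higher and 97 lower in pool10. With 1 extraction batch per pool size, batch and pool size cannot be told apart in that comparison.

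In the exposure from 13 December, feature 966 was 8.27-fold higher in pool10 (403 ± 68.4 CPM) than in pool1 (49.1 ± 61.96 CPM, SD, n = 8 each; edgeR adjusted p = 0.00528), with all 8 pools above the single-embryo mean. Feature 1394 was 6.96-fold higher (358 ± 25.1 against 51.9 ± 64.5 CPM; edgeR adjusted p = 0.00399), in 8 of 8 pools. Feature 1469 was 21.7-fold lower, at 3.28 ± 2.09 CPM in pool10 and 71.6 ± 74.8 CPM in pool1 (edgeR adjusted p = 0.00422), and all 8 pools lay below the single-embryo mean. Feature 2099 was 9.58-fold lower, at 178 ± 30.2 against 1729 ± 1806 CPM (edgeR adjusted p = 0.00630), again in 8 of 8 pools. In these 4 features the SD among single embryos was larger than their mean.

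Features differed between batches of 1 pool size in each of the pool sizes. By edgeR's F test over the 3 batches, 333 of 2692 features differed in pool1, 388 of 2733 in pool5, 2545 of 3045 in pool10 and 2236 of 3039 in pool20. DESeq2 called 526 in pool1 and 614 in pool5. Without samples 5 to 8 of batch 1, a setting added after the data were seen, edgeR called 35 in pool1. The pool5 batches shared 1 exposure and 1 extraction date. Batches 1 and 2 of pool5 differed in 0 of 2671 features (184 at an unadjusted p under 0.05, edgeR), while batch 3 differed in 450 features from each of batches 1 and 2. The median absolute log2 change was nearly alike between batches 1 and 2 (0.20) and between batches 2 and 3 (0.23), and was 0.35 between batches 1 and 3, while the coefficient of variation was 46.9%, 31.4% and 18.9% in batches 1, 2 and 3. The counts are not comparable as sizes of a batch effect, between pool sizes or between pairs of batches, since the spread within a batch and so the power differed. The median absolute log2 change between pairs of batches was 0.26 to 0.46 in pool1, 0.20 to 0.35 in pool5, 0.36 to 0.85 in pool10 and 0.27 to 0.37 in pool20.

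Samples of the same pool size and exposure differed between the extraction days of 23 and 24 November in both larger pools, a comparison added after the data were seen. Fitted together over 3086 features, 1611 features changed between the days in pool10 and 1153 in pool20. Of these, 924 were called in both, and 923 in both in the same direction, where independent lists would share 300.5 in the same direction. Across features, which are not independent replicates, the changes in pool10 and pool20 correlated at r = 0.85 with a covariance of 0.27. The 2 comparisons share no library. Without samples 5 to 8 of the batches of 23 November, 941 of 3109 features changed in pool10 and 763 in pool20, with r = 0.77.

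Feature 1967 fell 10.3-fold from 455 ± 90.9 to 44.6 ± 10.9 CPM in pool10 (SD, n = 8 each; edgeR adjusted p = 3.0e-12) and 13.5-fold from 398 ± 40.3 to 30.3 ± 5.67 CPM in pool20 (adjusted p = 6.8e-20). Feature 145 fell 4.65-fold in pool10, from 184 ± 49.3 to 39.8 ± 12.3 CPM, and 5.30-fold in pool20, from 197 ± 57.1 to 38.2 ± 12.1 CPM. Feature 2623 rose 3.71-fold in pool10, from 7.55 ± 4.46 to 28.4 ± 9.56 CPM, and 3.23-fold in pool20, from 6.23 ± 2.99 to 20.7 ± 6.23 CPM. Feature 592 rose 3.13-fold in pool10 and feature 1470 rose 3.07-fold in pool20. In each of these features all 8 samples of 24 November lay on the same side of the mean of 23 November.

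Between the exposures of pool10, 2383 of 3045 features changed, 1109 higher and 1274 lower in December, and exposure and extraction month changed together. Feature 1093 was 114-fold higher in December (343 ± 130 CPM, SD, n = 8) than in November (3.27 ± 0.79 CPM, n = 16; edgeR adjusted p = 1.5e-24). Feature 966 was 25.4-fold higher, at 403 ± 68.4 against 17.5 ± 7.36 CPM. Features 1057 and 2044 were 18.6-fold and 18.4-fold lower, at 0.85 ± 1.204 and 0.93 ± 0.73 CPM in December, close to the 0.899 CPM of 3 counts in the smallest library, against 18.7 ± 10.1 and 20.6 ± 8.94 CPM in November. All 8 December pools lay on the same side of the November mean in these 4 features.

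Between the extraction dates of pool20, all labelled with 1 exposure, 1827 of 3039 features changed, 858 higher and 969 lower on 15 December. The exposure is taken from the labels: the batch of 15 December lay between the November and the other December batches on the first axis, and whether its exposure label holds was not tested. Feature 1093 was 56.8-fold higher there, at 213 ± 54.7 CPM (SD, n = 8) against 3.93 ± 2.41 CPM (n = 16; edgeR adjusted p = 4.3e-25). Feature 1779 was 17.9-fold higher, at 30.5 ± 10.4 against 1.84 ± 1.89 CPM. Feature 2952 was 12.7-fold lower, at 1.53 ± 3.41 against 21.2 ± 10.6 CPM, and feature 1555 was 6.34-fold lower, at 2.86 ± 2.27 against 19.1 ± 7.73 CPM. All 8 later samples lay on the same side of the November mean in each.

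Between the exposures of pool1, 1 day apart, 234 of 2692 features changed, 114 higher and 120 lower in the later exposure. The later exposure was 1 extraction batch, extracted 1 day later, so exposure, extraction day and batch cannot be told apart. DESeq2 called 363. The count depended on the batch compared: batch 3 differed from batch 1 alone in 493 features and from batch 2 alone in 5. Without samples 5 to 8 of batch 1, a setting added after the data were seen, it was 66. Feature 1469 was 25.6-fold higher (71.6 ± 74.8 CPM, SD, n = 8, against 3.15 ± 5.82 CPM, n = 16, edgeR adjusted p = 0.00188), with 7 of 8 embryos above the earlier mean. The pool10 samples of that later exposure did not share this rise, with feature 1469 at 3.28 ± 2.09 CPM (SD, n = 8). Feature 2021 was 12.7-fold higher, at 29.2 ± 38.8 against 2.32 ± 3.24 CPM, in 7 of 8 embryos. Feature 2337 was 6.64-fold lower, at 37.3 ± 66.6 against 251 ± 119 CPM, and feature 2012 was 6.29-fold lower, at 7.42 ± 10.7 against 47.6 ± 39.01 CPM, each in 8 of 8 embryos.

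**Figure D4:**
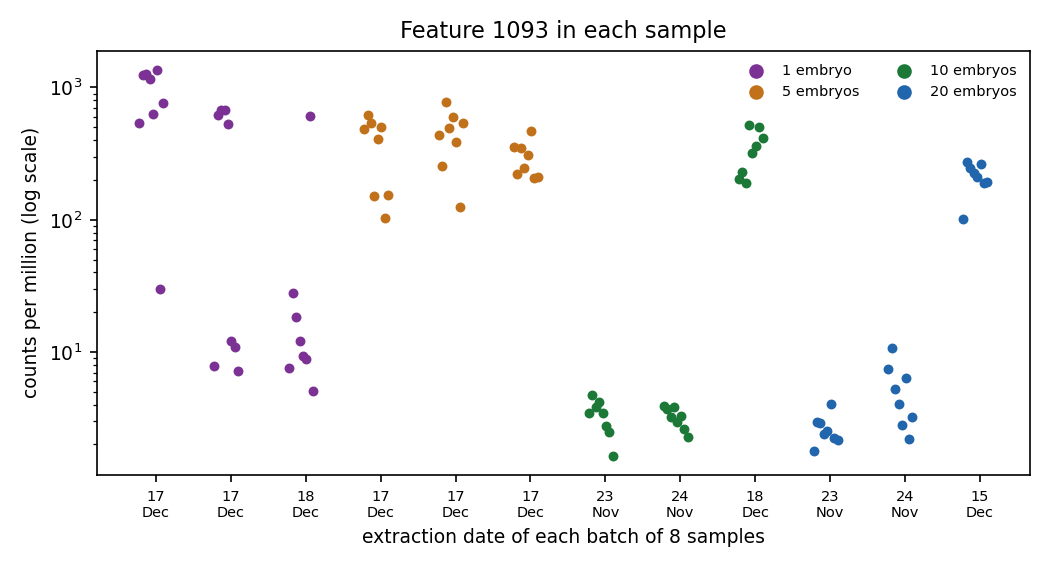
CPM (log scale) of feature 1093 in each of the 96 samples, by extraction batch and coloured by embryos per sample, with no error bars since every sample is shown. Pools of 10 and 20 embryos extracted in November average 2.62 to 5.25 CPM per batch and those extracted in December 213 and 343 CPM, while the 24 single embryos, all of December exposures, fall on both sides of a gap between 30.1 and 532 CPM.

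Within a batch, recovery of a known change was higher on average in larger pools, although single batches of 5, 10 and 20 embryos overlapped. All pool20 batches were November exposures and all pool1 and pool5 batches December ones. Pool size and exposure month therefore overlap in this comparison. With 4 against 4 samples of 1 batch and 200 features changed 2-fold in real counts, 6.71% ± 11.9 (SD, n = 12 splits) were recovered with single embryos, 39.5% ± 29.98 with pools of 5, 66.3% ± 11.2 with pools of 10 and 70.8% ± 5.25 with pools of 20. Splits reuse samples, so they describe these batches and were not tested. Pool1 gave 0% in batch 1, 5.5% in batch 2 and 14.6% in batch 3. 1 split of pool1 batch 3 gave 42.5%, with 247 calls outside the changed features, and without it, a value added after the data were seen, the mean was 3.45% with no other split above 9.5%. Pool5 ranged from 0% in batch 1 to 67.3% ± 0.65 (SD, n = 4 splits) in batch 3. Without the library that stands apart in batch 1, a setting chosen after the data were seen, that batch gave 25.5% ± 6.79 and pool5 47.96% ± 18.4. With 2 samples of positions 1 to 4 and 2 of positions 5 to 8 in each arm and position as a term, also added then, batch 1 gave 14.4% ± 2.56 in pool1 and 14.1% ± 16.3 in pool5 (SD, n = 4 splits each). Batches 2 and 3 were lower with that setting than without it, at 3.75% each in pool1 and at 42.1% and 65.25% in pool5. In the main setting pool10 gave 75.4% in batch 1, 52.8% in batch 2 and 70.9% in batch 3, and pool20 gave 74.9%, 70.5% and 66.9%. Batch 3 of pool5, at 67.3%, lay within the range of both larger pools.

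For a 1.5-fold change the shares were 2.00% ± 6.93, 14.9% ± 18.2, 28.3% ± 22.6 and 43% ± 5.01 for 1, 5, 10 and 20 embryos (SD, n = 12 splits each). Drawing the 4 against 4 samples across the 3 batches without a batch term lowered recovery of 2-fold changes to 2.08%, 26.8%, 11.4% and 46.96%. There pool10 lay below pool5, so the order by pool size did not hold across batches. Those draws spanned 1 exposure and 1 extraction date in pool5. In pool10 they spanned November and December exposures, and in pool20 different extraction dates. Calls outside the changed features had a median of 0, 6, 6 and 5 per split within a batch, and a maximum of 247, 14, 354 and 33, for 1, 5, 10 and 20 embryos. With positions balanced between the arms and position as a term, added after the data were seen, the maximum was 7, 13, 12 and 27.

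**Figure D5:**
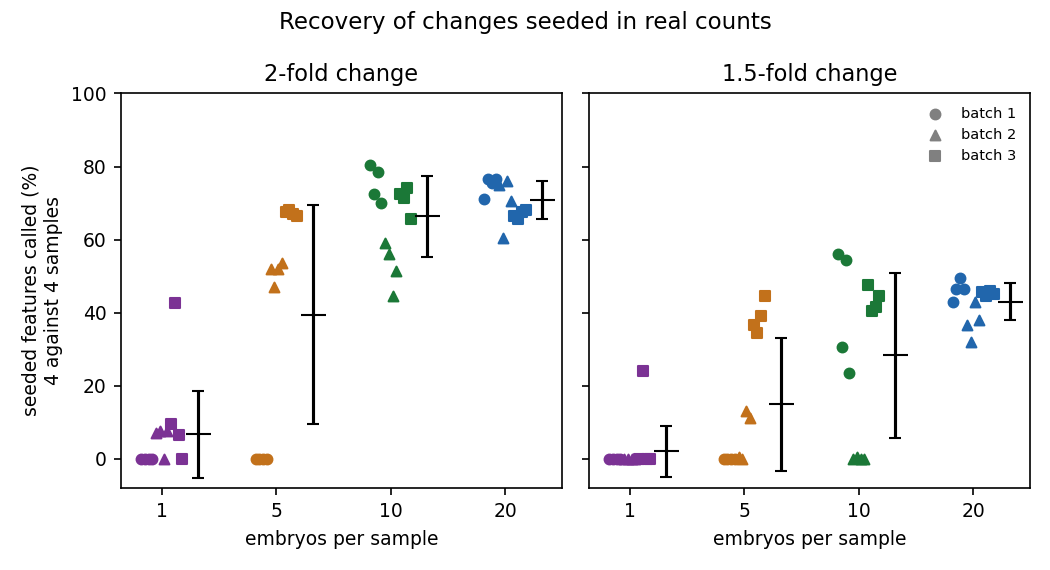
Share of 200 seeded features called (%) with 4 against 4 samples of 1 extraction batch, by embryos per sample, for a 2-fold change on the left and a 1.5-fold change on the right. Points are splits, shaped by batch, and black marks are the mean ± SD of 12 splits. For the 2-fold change the means are 6.71%, 39.5%, 66.3% and 70.8%, and the 4 splits of pool5 batch 1 all lie at 0%.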

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

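The tests of handling, of library order, of position in the batch, of counting error, of parents and of the depth of the pool5 library, and the settings without samples 5 to 8 of the number-1 batches, were chosen only after the results were seen, as were the definition of a gap and the choice of these patterns. Of 48 tests, each of 1 measure in 1 batch of 8 samples, 5 flagged a sample far from the others. About 1 in 20 is expected by chance for a normally distributed measure, and the measures were not checked for that. Sample 6 of pool5 batch 1, described below, was flagged in more than 1 of these tests. Sample 8 of pool5 batch 3 had 2701 detected features, below the next at 2742. The root mean square (rms) deviation from the batch mean on the log2 scale was 0.32 in sample 8 of pool10 batch 1, with the next at 0.27, and 0.54 in sample 4 of pool10 batch 2, with the next at 0.36.

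Sample 6 of pool5 batch 1 stood apart by an rms deviation of 1.19 against 0.28 to 0.60 in the other 23 pool5 samples, with 881 features over 2-fold from the batch mean against at most 194, and its 10 most abundant features took 35.7% of the counts against 30.4% in the next sample. Depth is argued against, since the 3 other pool5 libraries with totals at least as far from their batch mean had rms deviations of at most 0.48; an earlier test, whether its total lay outside its batch, had gone the other way (5280797 against 4278771 to 5070000), and one with thinned counts moved nothing. Position in the batch may account for the direction of its deviation, which correlated across features, which are not independent, at 0.74 with the difference of samples 5 to 8 from samples 1 to 4 in pool1 batch 1; its size stays open, as it lay 1.01 from the mean of samples 5 to 8 of its own batch, against at most 0.64 for the other 23 pool5 samples measured likewise. A pool of fewer embryos than labelled stays open: the library held 4 features below the gap between single embryos, as did the highest other pool5 sample and the lowest single embryo, and the prediction written beforehand, by which that value would have counted against fewer embryos, was set aside after the value was seen because both ranges reach 4. Its correlation of 0.75 with the first axis of the single embryos decides nothing between these, since that axis correlated at 0.97 with the same position difference, and no biological explanation was tested.

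The change between 23 and 24 November extraction differed between pool10 and pool20 in 2 of 3086 features by edgeR's interaction test (268 at an unadjusted p under 0.05), and 1 of 100 exchanges of the pool size, the real one, gave as many, with at most 1 in the others; without samples 5 to 8 of the number-1 batches it was 1 feature. Feature 915 fell in pool10 from 70.6 ± 10.1 to 27.96 ± 5.23 CPM and was 38.7 ± 7.54 and 45.6 ± 7.35 CPM in pool20 (SD, n = 8 each; edgeR adjusted p of the difference 1.1e-07, 8 of 8 pool10 samples). Feature 1896 rose in pool10 from 2.79 ± 0.66 to 9.11 ± 2.69 CPM and was 4.55 ± 0.63 and 5.29 ± 1.61 CPM in pool20 (adjusted p 0.0375 by edgeR, 8 of 8 pool10 samples). Each pool size had 1 extraction batch per day, and the sizes came from different exposures. Both the test and the exchanges used single samples as replicates, so pool size, batch and exposure cannot be told apart here.

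The shared part of that change was the larger one. Depth is argued against, since 1304 features were called with counts thinned to the smallest library against 1388 without, in batches labelled with 1 exposure, and so is the order of libraries by batch number, as the change from batch 1 to batch 2 in pool1 and pool5 correlated with that in pool10 and pool20 at 0.16 at most. Handling on the extraction day may account for it, as the changes in pool10 and in pool20, from other samples and another exposure, correlated at 0.85 across features, and at 0.77 without samples 5 to 8 of the number-1 batches. Storage of 1 day more and parents or dishes that differ between batches stay open and were not tested. Of 100 splits of single samples 1, the real one, gave as many features in pool10 (1388, highest other 696) and 1 in pool20 (1340, highest other 807), which leaves chance between batches open.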

How the results depend on the processing

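The exposure month as a covariate, the fit on pool1 and pool5 alone, the block for the exposure from 12 December the results without 1 pool5 library, position as a term and the results without samples 5 to 8 of the number-1 batches were chosen after seeing the data. Over 20 results, 91 of 118 alternative values kept their direction and side of the threshold, stayed within 1.5 times a count or within 1 SD of a share, and 27 did not; with 1 batch left out, 71 of 77 did. The cause was not tested, except where the setting itself changes the change, the samples or the replicate. The correlation of the coefficient of variation with pool size stayed between -0.96 and -0.91 with 1 batch left out, and that of detection between 0.83 and 0.91. The pool-size counts moved most. DESeq2 gave 251 features among the 4 sizes, 1 for pool5, 197 for pool10 and 129 for pool20 against pool1, where edgeR gave 0 each. Single samples without a batch term gave 1892, 161, 1455 and 1614, and the batch as a random effect gave 693, 649 for pool10 and 689 for pool20. With 1 batch left out they ranged from 0 to 772, 0 to 1, 0 to 953 and 0 to 265, each upper value without pool10 batch 3 except pool5's, which was without pool1 batch 3. Without pool10 batch 3 the larger pools were all November exposures and the smaller all December ones. With exposure month as a covariate the 4 counts stayed at 0. For pool5 against pool1 in the exposure from 12 December, DESeq2 gave 9 and single samples 157, against 0. DESeq2 also gave 526 for the pool1 batches, 614 for the pool5 batches and 363 between the pool1 exposures, where batch 1 alone gave 493 and batch 2 alone 5. Without samples 5 to 8 of the number-1 batches the pool1 batches gave 35 against 333 and the pool1 exposures 66 against 234, with 4 samples fewer in batch 1. Recovery of seeded changes in pool10 was 51.3% with 3 against 3, 11.4% across batches and 28.3% at 1.5-fold, and in pool20 63.3%, 46.96% and 43%. In the same settings pool1 gave 2.29%, 2.08% and 2.00% against 6.71%, and pool5 gave 29%, 26.8% and 14.9% against 39.5%. These counted as kept because the SD over splits was as large as 11.9 in pool1 and 29.98 in pool5. Counts that stayed at 0 counted as kept too. The tallies of 91 of 118 and 71 of 77 therefore do not measure how firm the results are. The planned removal of libraries under 1124677 counts removed 0 and gave no value.

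The replicate numbers did not pair the samples: batches of the same number had a median correlation of 0.24 over 18 pairs, from -0.37 to 0.80, against -0.13 over 36 pairs of different numbers, and 3 of the 12 batches were closest to their own number. The difference of samples 5 to 8 from samples 1 to 4 was nevertheless shared by the number-1 batches, with correlations of 0.39 to 0.79 over 6 pairs, and with position as a term the correlation of the coefficient of variation with pool size was -0.94. With the replicate block the 4 pool-size counts stayed at 0, and pool5 against pool1 in the exposure from 12 December rose from 0 to 144 with 1 residual degree of freedom. Position in the batch as a block gave 168 features for pool10 against pool1 in the exposure from 13 December, against 193, split as 116 higher and 52 lower over 2895 features tested where the fit without it had 96 and 97 over 2567, and moved no other total by over 1.5 times. Depth limits features near 3 counts, which is 0.899 CPM in the smallest library.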

Other observations

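The comparison by abundance, the definition of a gap, the number of pairs able to pass the association test and the tests of counting error and of parents were chosen after the data were seen. In libraries extracted in November, features of low abundance lay higher and those of high abundance lower than in later libraries of the same pool size, as values with no test. With features in 4 groups by abundance in pool5, the November pool10 samples lay 0.67 ± 0.18 log2 units above the December ones in the least abundant group and at -0.59 ± 0.21 in the most abundant (SD, n = 16). In pool20 these values were 0.27 ± 0.09 and -0.21 ± 0.09. All pool5 samples were extracted in December, so features that were higher in December for any reason tend to rank as abundant. Part of the pattern is therefore built into the grouping, and how large that part is was not tested.

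Of 2198 features, 20 had a gap of at least 3 log2 units between single embryos with at least 3 embryos on each side, against 0 in pool5, 2 in pool10 and 2 in pool20. For the 20 features with a gap between single embryos, counting error is argued against by a median of 689 counts above the gap and 11.5 below it. Depth is argued against by a Spearman rho of 0.23 (permutation p = 0.285, 24 embryos) between the total and the number of features below the gap. A state that sets these features together is argued against, as 0% of 136 pairs of the 17 features with a gap among the 16 embryos of 1 exposure were associated, where 90 pairs could have been and shuffled states gave 0.29% on average; a weaker link is not excluded. Inherited variants at unlinked loci may account for the gaps, as a hypothesis that predicts the same 0%, and a state set at random for each feature predicts it equally. Parents that differ between batches stay open: the change of these features lay at percentile 99.85 of 10000 lists between pool20 extraction dates, at 100 and 95.8 between 23 and 24 November in pool20 and pool10, at 99.4 between pool10 exposures and at 94.1 and 87.2 between pool5 batches, but the lists were matched on mean expression only, and features chosen for their spread would move more under any cause.

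Feature 1093, with the widest gap among those 20, was at 532 CPM or more in 12 single embryos and at 30.1 CPM or less in 12. The embryos above the gap were 7 of 8 in pool1 batch 1, 4 of 8 in batch 2 and 1 of 8 in batch 3, with batch means of 871, 318 and 87.9 CPM. It was at 213 ± 54.7 CPM in the pool20 batch of 15 December and at 2.62 ± 0.68 and 5.25 ± 2.83 CPM in the pool20 batches of November (SD, n = 8 each), all labelled with 1 exposure, a label that was not tested.

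Other splits of the same samples were counted for each model, at most 100 per result. Among the 4 pool sizes 100 of 100 splits gave at least the real count of 0, as any split must, so this decides nothing; the highest of the others gave 620. For pool5, pool10 and pool20 against pool1 all 10 splits gave at least the real count of 0; 10 are too few for a share under 0.05, and the highest other counts were 0, 617 and 0. The split with 617 set the November pool10 batches with pool1 batch 1 against the rest. The other results were split by single samples, which leaves chance between extraction batches open, since 3 against 3 batches or fewer allow no share under 0.05. A low share in these splits argues against chance between samples but does not exclude it. Samples of a batch are not all alike, and other splits gave up to 913 features. There 1 of 100 splits, the real one, gave as many for pool10 against pool1 in the exposure from 13 December (193, highest other 2), the batches of pool1 (333, 14), pool10 (2545, 871) and pool20 (2236, 344), the exposures of pool10 (2383, 913) and pool1 (234, 96), the extraction dates of pool20 (1827, 1), features less variable in pool20 (2049, 0), and pool5 batch 3 against batches 1 and 2 (450 each, 352 and 344). For the batches of pool5, 2 of 100 splits gave as many as the real 388, the other giving 779. Without the pool5 library that stands apart the real count was 408.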
